A study of Mus musculus with 6 samples.

How the data were processed

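The series holds RNA sequencing of mouse embryonic fibroblasts, 3 libraries from beta-actin knockout cells (KO) and 3 from wild-type cells (WT), all taken after 6 days in adipocyte differentiation medium. The labels give the strain as BALB/c. RNA was extracted with TriZol LS and RNeasy, and libraries were made with the TruSeq RNA Library Prep Kit v2. The deposited files hold raw read counts per Ensembl mouse gene, 1 library in each, as the authors made them. The submitters' processing notes name TopHat2 2.1.0, HTSeq, DESeq2 and the genome build GRCm38.p4. The annotation release, the strand setting and any filter on reads are not given in the sources used here. Each library lists the same 46603 gene identifiers, of which 46005 matched a GENCODE annotation of GRCm38 by Ensembl identifier and 598 did not. Symbols, positions, GC content and exon length came from that annotation, and 99.66% of tested genes had a GC content and a length. Where a gene is said to overlap another, their gene bodies overlap, and overlap of exons was not examined.

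Counts were analysed in R 4.3.3. Genes were kept with edgeR 4.0.16 filterByExpr by group, libraries were scaled with TMM, and KO was compared with WT by the edgeR quasi-likelihood F test, two-sided, with group as the only term. A gene counted as changed at a Benjamini-Hochberg adjusted p below 0.05 over all tested genes, and the count at an absolute log2 fold change of at least 1 is given beside it. Log2 fold changes are KO over WT. The standard error printed with each is that of the difference in mean log2 CPM (counts per 1e6 in TMM-scaled libraries), with n = 3 per group, and CPM values are mean ± SD. Gene lists and chromosomes were tested as sets with camera on voom values (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists or over the 20 chromosomes. Camera asks whether a set moved relative to all other genes. At this preset, groupings that mix KO and WT libraries also gave 4 to 8 lists past the test, against 7 for KO and WT. Such groupings keep part of the KO to WT difference, so they do not give a rate of false calls. The count of changed members is given over all genes and adjusted over the list alone. The share of changed genes within 5 Mb of Actb, Actb left out, was compared with the other tested genes by Fisher's exact test, two-sided.

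The tests, the lists, the alternatives and the rule for naming genes were chosen before the data were examined, except where stated. The rule names the 6 actin isoform genes, 8 adipogenic markers, the 8 largest changes in each direction, and members of each list. The largest changes were taken among changed genes with a mean count of at least 200 in the higher group, no overlap of KO and WT values, and a symbol that is not a predicted, clone or pseudogene name. From each list the rule takes the 3 changed members with the smallest p, plus 1 in the other direction where there is one, and 1 gene that it takes is not reported here. The 29 lists cover adipogenic transcription factors, adipocyte lipid storage and secreted products, fatty acid synthesis, cholesterol synthesis, brown and beige fat, preadipocyte and anti-adipogenic genes, actin isoforms, SRF-MRTF and contractile genes, YAP-TEAD targets, collagens and matrix, osteoblast, chondrocyte, neuronal and skeletal muscle genes, SWI-SNF (BAF) subunits, Polycomb repressive complexes, Hox genes, glucocorticoid-induced and cAMP-CREB induced genes, cell cycle, interferon response, inflammatory cytokines, mitochondrially encoded and nuclear-encoded respiratory chain genes, p53 targets, macrophage, endothelial and epithelial markers, and genes that tell the sex of an embryo. Another 4 lists, on MHC class I, glycolysis, the ATF4 amino acid response and imprinted genes, were chosen after the values had been seen.

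Alternatives were RLE, upper-quartile and library-total scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a CPM of at least 1 in 3 libraries, the 10 most abundant genes left out, the replicate number as a block, per-library GC and length offsets, a test against a log2 fold change of 1 (glmTreat), each library left out in turn, fry or an estimated correlation for the sets, and other distances from Actb. A fit without 1 library has fewer libraries in a group and thus less power. A call lost there need not mean that the library left out made the result. Counts of list members without KO replicate 1 and under each other setting, the GC offset for chromosomes, and the other genes of chromosome 5 as a background for Actb were added after the data were seen. The replicate number was not a term of the model, since the labels do not pair the cultures and the deviations of equally numbered KO and WT libraries from their group means correlated, across genes, at only -0.101, 0.046 and -0.148.

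Library totals ran from 26955708 to 38619711 counts. A count of 3, taken as the limit that a count of 0 allows, is 0.0777 to 0.111 CPM by library. This range is on library totals before TMM scaling, while the fold bounds at a floor of 3 counts use TMM-scaled CPM. Intervals on ratios with 1 to 3 counts in a group are exact binomial at 95%. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The labels do not say whether the 3 libraries of a genotype are separate cultures, so the p-values may measure technical spread alone, and genotype and cell line cannot be separated. The pipeline was tested on simulated counts with 200 changed genes and the depth and spread of these libraries. It called 8.2% of genes changed by 0.585 log2, 31.2% at 1, 85.1% at 2 and 100% at 3, with 11 false calls among 14571 unchanged genes (9.2% of the calls). With no simulated change it called 0 of 14770 genes. A simulated list and a simulated chromosome shift were recovered with adjusted p = 1.86e-45 and 3.4e-23. Genes were drawn independently of each other, so this recovery does not show how the set tests behave with correlated genes. The call rates hold for 200 changed genes, against 4255 called in these data.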

Results

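Gene expression was measured by RNA sequencing in mouse embryonic fibroblasts (MEFs) that lack beta-actin (KO) and in wild-type MEFs (WT), 3 libraries each, after 6 days in a medium with insulin, dexamethasone, IBMX and ascorbic acid that drives fibroblasts toward the adipocyte fate. The WT libraries held 30235906, 29850826 and 26955708 counts and the KO libraries 30240750, 34990950 and 38619711. Between 20870 and 22198 genes had at least 1 count in a library, and mitochondrial transcripts took 3.57% to 3.64% of counts in WT and 3.76%, 5.41% and 4.43% in KO replicates 1, 2 and 3.

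The comparison of KO with WT cells asks which genes differ in expression between the genotypes after 6 days in this medium. The series holds no library from before induction. Differences already present then cannot be told apart from changes during adipogenesis. In KO cells, Actb transcripts fell to 39.9 ± 25.9 from 1875 ± 47.9 CPM (SD, n = 3) while the gamma and smooth muscle actins rose. In the SRF-MRTF and contractile list 17 of 23 genes rose, such as Cnn1, which encodes calponin, and in the collagen and matrix list 17 of 30 rose, such as Col3a1, and 2 fell (each list adjusted p = 0.317 with an estimated correlation). Of the p53 targets 10 of 15 fell, of the interferon-response genes 9 of 19, and of the brown and beige fat genes 8 of 11 with 1 higher (adjusted p = 0.39, 0.317 and 0.317 with an estimated correlation). Adipogenic genes differed in both directions, with Pparg and Lpl, for lipoprotein lipase, higher and Cebpa lower in KO. Adipoq and Plin1 were at the limit of detection in both genotypes. Neither the adipogenic transcription factors nor the lipid storage list passed camera as a set (adjusted p = 0.316 and 0.244). With fry, which does not compare a list with other genes, the first passed (adjusted p = 0.00139) and the second did not (0.192).

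The 6 actin genes encode cytoplasmic, smooth muscle and striated muscle isoforms. Actb (ENSMUSG00000029580, chromosome 5, 142903115 to 142906754, GRCm38) had 60501, 60582 and 53894 counts in WT and 276, 1988 and 1850 in KO replicates 1, 2 and 3. Its log2 fold change was -5.55 (SE 0.80, adjusted p = 0.00088), 46.95-fold lower. Actg1, the other cytoplasmic isoform (ENSMUSG00000062825, chromosome 11), rose by 1.45 log2 (SE 0.08, adjusted p = 0.000524), from 1204 ± 20.7 to 3293 ± 328 CPM. Its sequence is close to that of Actb, so reads shared by both are assigned with less certainty. Acta2, smooth muscle alpha-actin (ENSMUSG00000035783, chromosome 19), rose by 6.88 log2 (SE 0.48, adjusted p = 0.000136), from 62.3 ± 16.6 to 7327 ± 3771 CPM. Actg2, smooth muscle gamma-actin (ENSMUSG00000059430, chromosome 6), rose by 9.51 log2 (SE 0.47, adjusted p = 3.23e-05), from 0.270 ± 0.098 to 198 ± 80.6 CPM. Acta1 had 5 counts in WT and 49 in KO over the 3 libraries, and Actc1 had 2 and 0, both too few for the test. Of the 4 tested isoforms 3 rose and 1 fell, 4 adjusted over the list alone, and the list as a set had adjusted p = 0.0505, or adjusted p = 0.317 with an estimated correlation. Without WT replicate 1, WT replicate 2 or KO replicate 3 the set's adjusted p was 0.0458, 0.0399 and 0.0355.

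**Figure D1:**
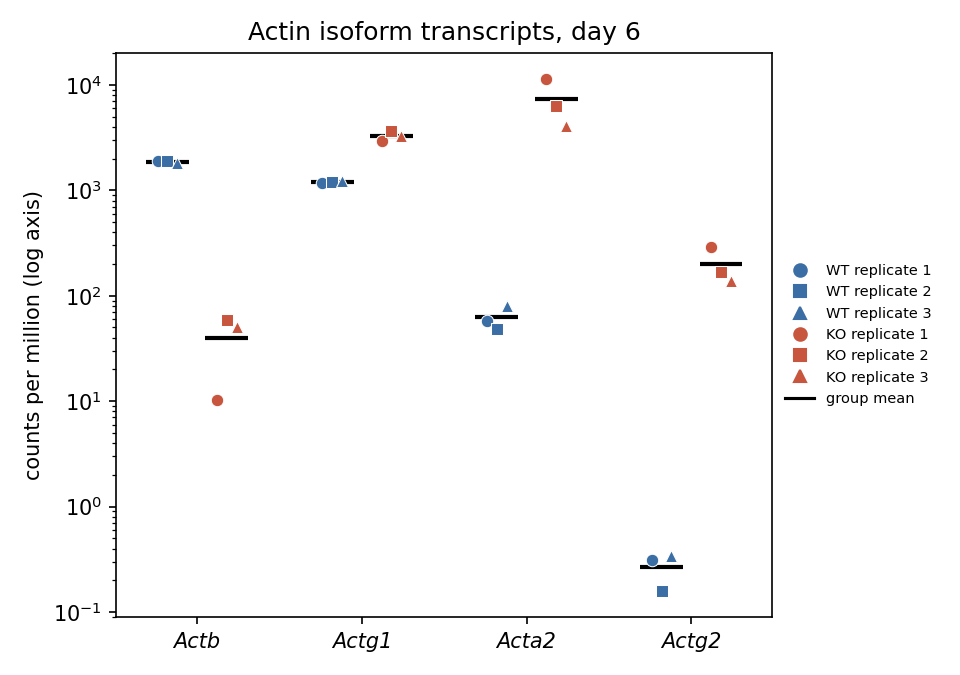
CPM (log axis) of the 4 tested actin isoforms in each library, with symbols for replicates and black bars for the group means. The KO mean of Actb lies at 39.9 against 1875 CPM in WT, and the KO means of Actg1, Acta2 and Actg2 lie above those of WT.

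Genes that drive adipogenesis were split. Of 18 tested adipogenic transcription factors 3 rose, 5 fell and 10 were not called (8 adjusted over the list alone). Pparg, the master regulator of adipocyte differentiation, rose by 0.73 log2 (SE 0.19, adjusted p = 0.0205), from 16.0 ± 2.42 to 26.6 ± 4.18 CPM, and Ebf1 rose by 2.01 log2. Cebpa, its partner in the mature program, fell by 4.20 log2 (SE 0.78, adjusted p = 0.000813), from 5.59 ± 0.37 to 0.290 ± 0.186 CPM, and Zfp423, a preadipocyte commitment factor, had 0 counts in KO against 150 in WT, at least 16.98-fold lower at a floor of 3 counts per library. The early factors Cebpb (log2 fold change 0.30, adjusted p = 0.26) and Cebpd (0.70, adjusted p = 0.277) were not called. Both genes overlap the body of another gene on the opposite strand. An unstranded library cannot separate reads of exons shared in this way, but whether exons overlap was not examined. As a set the list had adjusted p = 0.316 with camera and adjusted p = 0.00139 with fry. Pparg lost its call without WT replicate 1 (adjusted p = 0.0813), WT replicate 2 (0.0845) or KO replicate 2 (0.0523) and with library-total scaling (0.0628), and Cebpd gained one without KO replicate 2 (1.06 log2, 0.0387), against 0.135 log2 without KO replicate 1 (0.764).

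Many products of the mature adipocyte were near the limit of detection. In the list of lipid storage genes and secreted products 17 of 27 had counts enough to test, of which 5 rose, 2 fell and 10 were not called (10 called adjusted over the list alone), and the set had adjusted p = 0.244. Lpl rose by 5.70 log2 (SE 0.53, adjusted p = 0.000124), from 2.74 ± 1.44 to 142 ± 4.86 CPM. Angptl4, an inhibitor of lipoprotein lipase, fell by 8.66 log2, from 100.1 ± 17.1 to 0.229 ± 0.168 CPM, and Lipe, hormone-sensitive lipase, fell by 1.94 log2. Fabp4, the fatty acid binding protein of adipocytes, had 304, 152 and 246 counts in WT and 2914, 290 and 597 in KO (log2 fold change 2.57, SE 1.14, adjusted p = 0.0686). Without KO replicate 1 its log2 fold change was 0.72 (adjusted p = 0.119). It passed the test without KO replicate 2 (adjusted p = 0.0198) or KO replicate 3 (0.0483) and with no filter on low counts (0.0127), and missed it in the other alternatives, the highest with limma-voom (0.236). Adipoq, which encodes adiponectin, had 0 counts in WT and 1 in KO, Plin1, for perilipin, 5 and 6, and Lep, for leptin, 0 in all 6 libraries. Cidec had 0 counts in each WT library and 0, 3 and 45 in KO. The number of higher genes in this list was 3, 2 and 3 without WT replicates 1, 2 and 3 and 8 without KO replicate 1.

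Genes of brown and beige fat were lower as a set. Of 11 tested 8 fell, 1 rose and 2 were not called (10 called adjusted over the list alone), with a median of -2.34 log2 and adjusted p = 0.00281, or adjusted p = 0.317 with an estimated correlation. Zic1, a marker of brown fat and of neural precursors, fell by 9.48 log2 from 46.5 ± 1.77 to 0.0544 ± 0.0942 CPM, and Elovl3, a fatty acid elongase, fell by 2.65 log2. Tnfrsf9 rose by 2.86 log2. Zic1 and Tnfrsf9 each overlap a neighbour on the opposite strand. Ucp1, the uncoupling protein of thermogenic fat, had 7 counts in WT and 5 in KO, Cidea had 2 and 0, and Cox8b had 0 in both. Several of the tested genes were near the floor. With the filter of a CPM of at least 1 in 3 libraries 6 genes of the list were left, 4 lower and 1 higher. The number of lower genes was 4 without WT replicate 1 and 5 without WT replicate 3. Preadipocyte and anti-adipogenic genes went both ways, with 4 higher, 4 lower and 13 not called of 21 (8 adjusted over the list alone, set adjusted p = 0.899). Their median was 0.15, their mean -0.17 and the set's direction up, and the median was -0.04 with library totals. The surface marker Cd34 fell by 7.28 log2, the Wnt inhibitor Sfrp1 fell by 4.65, and Ly6a, for the stem cell antigen Sca-1, rose by 4.55, or 3.75 without KO replicate 3. Without KO replicate 1 the counts of this list were 7 higher and 6 lower.

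In lipid synthesis, 3 of 13 fatty acid genes rose, 1 fell and 9 were not called (4 adjusted over the list alone, set adjusted p = 0.893). The desaturases Scd1 and Scd2 rose by 1.03 and 1.06 log2, and Mlxipl, the carbohydrate-response transcription factor, fell by 4.90. The list had a median of -0.10 and a mean of -0.21 while its set direction was up. Without KO replicate 1 its median turned positive and 5 genes were higher. With library totals the median was -0.311, with 2 genes higher and 2 lower. Of 20 cholesterol synthesis genes 6 rose and 14 were not called (7 called adjusted over the list alone), among them Hsd17b7 (1.36 log2), Hmgcs1 (0.54) and Sqle, for squalene epoxidase (0.60). This set had adjusted p = 0.0168, or adjusted p = 0.646 with an estimated correlation, 0.117 with fry, 0.0569 without WT replicate 3 and 0.2 without KO replicate 1. Its counts were 2, 1 and 2 higher without WT replicates 1, 2 and 3, 3 higher without KO replicate 3, 7 higher and 3 lower without KO replicate 1, and 3 higher and 1 lower with library totals. Sqle lost its call without WT replicates 1, 2 or 3 (adjusted p = 0.0614, 0.0731 and 0.0835), and Hmgcs1 without WT replicate 2 (0.0537).

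Genes controlled by SRF and MRTF, which respond to the actin pool, were higher as a set. Of 23 tested 17 rose, 0 fell and 6 were not called (20 called adjusted over the list alone), with a median of 1.11 log2 and adjusted p = 3.74e-10, or adjusted p = 0.317 with an estimated correlation. Cnn1 rose by 7.86 log2 (SE 0.33, adjusted p = 1.93e-05), from 0.777 ± 0.207 to 181 ± 50.4 CPM. Lmod1, leiomodin, rose by 6.83 (from 0.723 ± 0.250 to 82.1 ± 24.5 CPM) and Myl9, a myosin light chain, by 4.68 (from 35.7 ± 10.4 to 918 ± 191 CPM). Collagens and other matrix genes were higher as a set as well, with 17 higher, 2 lower and 11 not called of 30 (23 called adjusted over the list alone), a median of 1.01 log2 and adjusted p = 2.25e-05, or adjusted p = 0.317 with an estimated correlation. Col3a1 rose by 5.04 log2 (from 31.0 ± 12.2 to 1021 ± 194 CPM), Col1a2 by 4.30 and the basement membrane collagen Col4a2 by 1.43, while Col11a1 fell by 4.90. Col4a2 overlaps Col4a1 on the opposite strand. The 2 lower genes became 1 without WT replicate 1, WT replicate 3 or KO replicate 3. YAP-TEAD targets split, with 4 higher, 3 lower and 8 not called of 15 (7 adjusted over the list alone, set adjusted p = 0.316). Tissue factor F3 and the ecto-nucleotidase Nt5e rose by 3.03 and 2.02 log2, and Ajuba fell by 1.20. Without KO replicate 1 F3 was 2.31 log2 higher and this list had 5 higher and 5 lower.

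**Figure D2:**
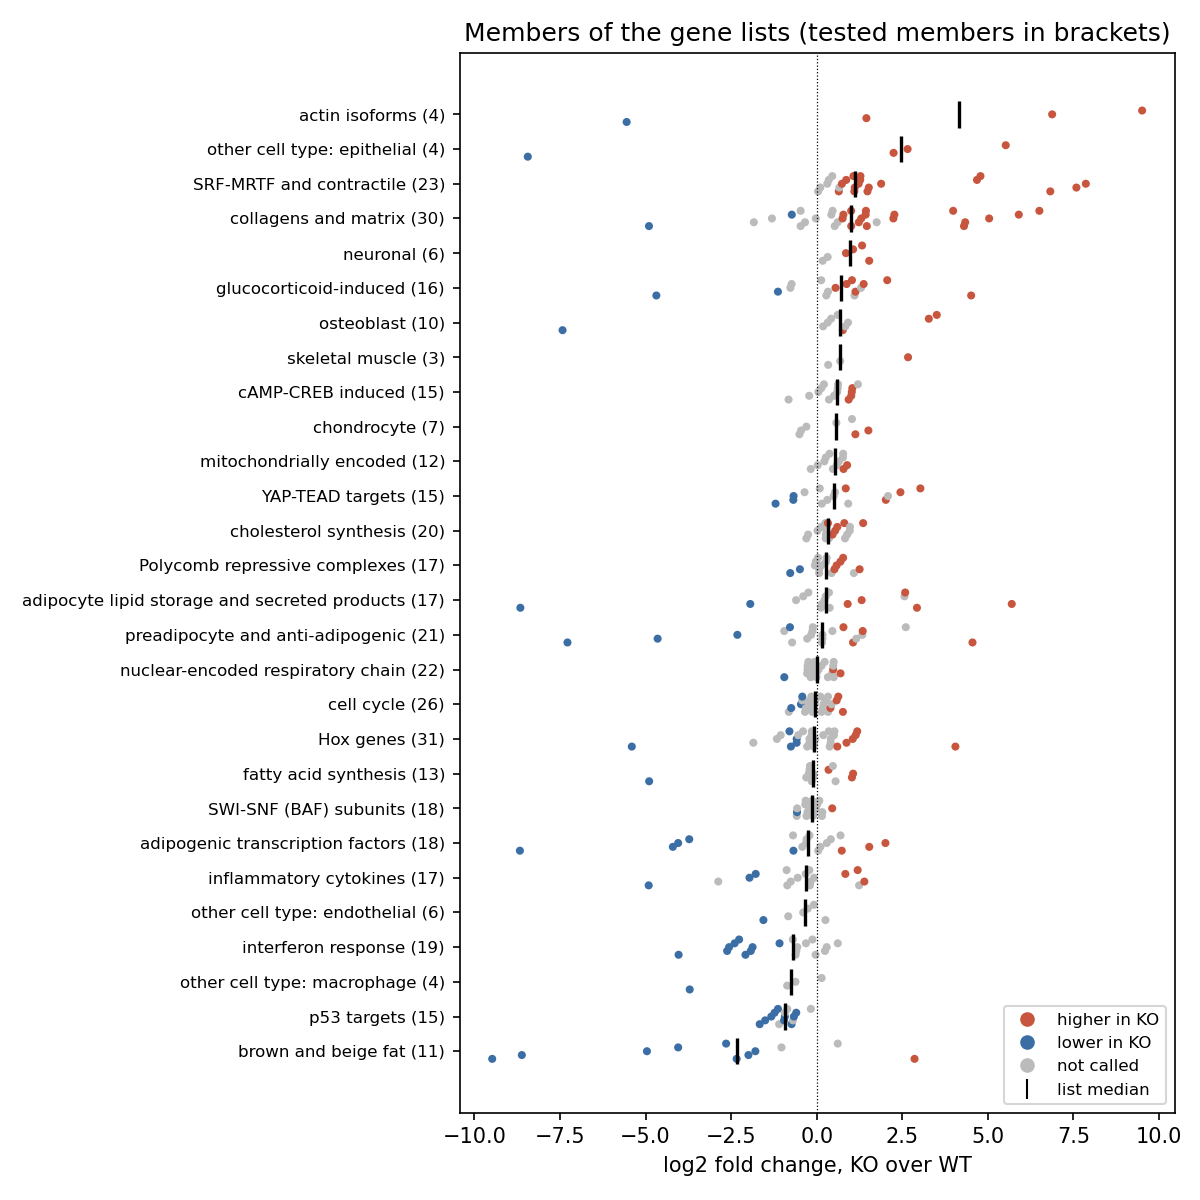
Log2 fold change (KO over WT) of each tested member of the 28 lists with tested members, ordered by list median (black bars), coloured by call. The SRF-MRTF list has its 17 called members on the higher side, and the p53 list its 10 called members on the lower side.

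Among genes of other mesenchymal and neural fates, of 10 tested osteoblast genes 3 rose, 1 fell and 6 were not called (4 adjusted over the list alone, set adjusted p = 0.0618). The homeobox gene Msx2 rose by 3.51 log2 and Spp1, osteopontin, by 3.28, from 169 ± 59.1 to 1635 ± 690 CPM, though a predicted gene overlaps Spp1 on the same strand. Bmp2 had 386 counts in WT and 2 in KO, a ratio of 201 (95% interval 55.27 to 1666), with both KO counts in KO replicate 3. The osteoblast set passed without WT replicate 1 (adjusted p = 0.0413), and 2 genes were lower without WT replicate 3. Of 6 tested neuronal genes 4 rose and 2 were not called (4 adjusted over the list alone, adjusted p = 0.0195, or adjusted p = 0.317 with an estimated correlation). Map2, Ncam1 and Syt1 rose by 1.06, 0.86 and 1.53 log2, and the neuronal determinants Neurod1 and Myt1l had 0 counts in all 6 libraries. This call was lost without WT replicate 2 (adjusted p = 0.0746), KO replicate 1 (0.0622), KO replicate 2 (0.122) or KO replicate 3 (0.131), where 1 gene was also lower. Of 7 chondrocyte genes 2 rose and 5 were not called (2 adjusted over the list alone, set adjusted p = 0.59), Matn3 by 1.51 log2 and Prg4, which overlaps Tpr on the opposite strand, by 1.13. Both lost their calls without WT replicate 1 (adjusted p = 0.148 and 0.158), WT replicate 2 (0.162 and 0.0829), KO replicate 1 (0.0533 and 0.0567) or KO replicate 3 (0.0596 and 0.1), Prg4 also without WT replicate 3 (0.144), and both with library totals (0.0642 and 0.0742) and a GC offset (0.0506 and 0.0544), Prg4 also with upper-quartile scaling (0.0523) and limma-voom (0.0786). The list had 0 calls without WT replicate 1, WT replicate 2 or KO replicate 3 and with a GC offset, 1 lower gene without KO replicate 1, and 0 higher and 1 lower with library totals. Tnnt3, a troponin, rose by 2.67 log2 from 10 to 67 counts and was the only called gene of 3 tested for skeletal muscle (1 adjusted over the list alone, set adjusted p = 0.217).

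Markers of other cell types were scarce. Only 4 of 14 macrophage genes could be tested, of which Fcer1g fell by 3.71 log2 from 55 to 4 counts and 3 were not called (1 adjusted over the list alone, set adjusted p = 0.237). Of 6 tested endothelial genes Vwf fell by 1.56 log2 and 5 were not called (1 adjusted over the list alone, set adjusted p = 0.27). Vwf lost its call without WT replicates 1, 2 or 3 (adjusted p = 0.0772, 0.106 and 0.0793) or KO replicate 2 (0.0568). Of 4 tested epithelial genes 3 rose and 1 fell (4 adjusted over the list alone, set adjusted p = 0.297). The keratins Krt18 and Krt19 rose by 5.52 and 2.66 log2, and the adhesion molecule Epcam had 127 counts in WT and 0 in KO, at least 14.46-fold lower. Without KO replicate 1 Krt18 was 4.75 log2 higher, and the log2 fold change of Fcer1g was -4.89 without KO replicate 2 and -3.08 without KO replicate 3. Without KO replicate 1 the lower genes were 2 for macrophage, 3 for endothelial and 2 for epithelial markers, the last also without KO replicate 2. Genes that tell the sex of an embryo were below the filter, with 4 to 15 counts of Xist in each library, 0 of Ddx3y and Eif2s3y, 2 and 11 of Uty and 4 and 1 of Kdm5d in WT and KO.

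Among chromatin regulators, few subunits of the remodelling complexes changed. Of 18 tested SWI-SNF (BAF) subunits Actl6a, an actin-related subunit, rose by 0.45 log2, Pbrm1 fell by 0.58 and 16 were not called (1 adjusted over the list alone, set adjusted p = 0.279). Both genes overlap neighbours on the opposite strand. Actl6a lost its call without any 1 library except KO replicate 1 (adjusted p = 0.0549, 0.16 and 0.127 without WT replicates 1, 2 and 3, 0.104 and 0.112 without KO replicates 2 and 3) and with library totals (0.216), upper-quartile scaling (0.0732) and no filter (0.0589), and Pbrm1 without WT replicate 2 (0.0767) or WT replicate 3 (0.0611). The BAF counts without KO replicate 1 were 2 higher and 3 lower, without KO replicate 2 they were 0 and 3, with library totals 0 and 4, and with upper-quartile scaling 0 and 3. Of 17 Polycomb genes 5 rose, 2 fell and 10 were not called (7 adjusted over the list alone, set adjusted p = 0.0809). Jarid2 and Cbx8 rose by 1.25 and 0.69 log2, and Ring1 fell by 0.49. Ring1 lost its call without WT replicate 1 (adjusted p = 0.0517), WT replicate 2 (0.0731), KO replicate 2 (0.0512) or KO replicate 3 (0.0627) and with a GC offset (-0.34 log2, 0.0664), and Cbx8 without WT replicate 2 (0.0547). Polycomb counts, higher and lower, were 3 and 0, 2 and 0, and 4 and 1 without WT replicates 1, 2 and 3, and 9 and 2, 6 and 1, and 5 and 0 without KO replicates 1, 2 and 3, with 3 and 2 under library totals and 4 and 0 with a GC offset. Of 31 Hox genes 6 rose, 5 fell and 20 were not called (15 adjusted over the list alone, set adjusted p = 0.893, direction up against a median of -0.09). Hoxa9 rose by 1.18 log2, Hoxa11, which overlaps an antisense transcript, fell by 5.40, and Hoxd4 had 3 counts in WT and 57 in KO, a ratio of 18.2 (95% interval 5.94 to 91.1). Hox counts were 3 and 2, 2 and 1, and 3 and 2 without WT replicates 1, 2 and 3, 9 and 8 without KO replicate 1, 3 and 3 without KO replicate 3, 3 higher and 9 lower with library totals, and 7 and 3 with a GC offset. Of the KO counts of Hoxa11, 5 of 6 lay in KO replicate 3, and of the WT counts of Hoxd4, 2 of 3 lay in WT replicate 1.

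Targets of p53 were lower as a set. Of 15 tested 10 fell, 0 rose and 5 were not called (13 called adjusted over the list alone), with a median of -0.93 log2 and adjusted p = 3.98e-06, or adjusted p = 0.39 with an estimated correlation. Ccng1, cyclin G1, fell by 1.67 log2 (from 495 ± 61.8 to 156 ± 23.6 CPM), the stress protein Sesn2 fell by 1.23, and Cdkn1a, the p21 inhibitor of cell cycle kinases, fell by 1.13 (from 286 ± 47.9 to 131 ± 15.8 CPM). Of 26 cell cycle genes 4 rose, 3 fell and 19 were not called (7 adjusted over the list alone, set adjusted p = 0.899, direction up against a median of -0.05). The direction of the cell cycle set was down without KO replicate 1. The mitotic kinases Plk1 and Aurka rose by 0.58 and 0.63 log2, and the transcription factor E2f1 fell by 0.74. Aurka lost its call without WT replicates 1, 2 or 3 (adjusted p = 0.0623, 0.0663 and 0.0823), Plk1 with library totals (0.053) and E2f1 with a GC offset (0.051). Cell cycle counts, higher and lower, were 1 and 2, 1 and 1, and 1 and 1 without WT replicates 1, 2 and 3, 5 and 6, 4 and 1, and 3 and 1 without KO replicates 1, 2 and 3, 2 and 7 with library totals, and 3 and 0 with a GC offset.

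Interferon-response genes were lower as a set, with 9 lower, 0 higher and 10 not called of 19 (9 adjusted over the list alone), a median of -0.70 log2 and adjusted p = 0.0029, or adjusted p = 0.317 with an estimated correlation. The chemokine Cxcl10 fell by 2.62 log2 (from 10.1 ± 3.20 to 1.63 ± 0.71 CPM) and the transcription factor Irf9, which overlaps Rnf31 on its own strand, fell by 1.87. Oas1a had 53 counts in WT and 3 in KO, a ratio of 18.4 (95% interval 5.96 to 92.1), with 2 of the 3 KO counts in KO replicate 3 and a log2 fold change of -4.77 without that library against -4.04 with it. Inflammatory cytokine genes split, with 3 higher, 3 lower and 11 not called of 17 (7 adjusted over the list alone, set adjusted p = 0.234). The adhesion molecule Icam1 fell by 4.91 log2, Lif fell by 1.96, Saa3, serum amyloid A, fell by 1.78, and Ptgs2, cyclooxygenase, rose by 1.20. Saa3 lost its call without WT replicate 1 (adjusted p = 0.0511) and Ptgs2 without WT replicate 2 (0.0749) or WT replicate 3 (0.0753). Icam1 was at -5.99 log2 without KO replicate 2 and -4.27 without KO replicate 3. The cytokine counts were 0 and 3 without WT replicate 2, 0 and 4 without WT replicate 3, 3 and 5 without KO replicate 2, 1 and 5 without KO replicate 3, 1 and 5 with library totals, 1 and 4 with upper-quartile scaling, and 1 and 3 with a GC offset.

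Genes that answer the components of the medium rose in part. Of 16 glucocorticoid-induced genes 7 rose, 2 fell and 7 were not called (11 adjusted over the list alone, set adjusted p = 0.121). Hif3a rose by 4.51 log2, from 10 to 237 counts, while Zbtb16, a marker of dexamethasone response, fell by 4.69 from 17.9 ± 6.19 to 0.686 ± 0.613 CPM, and Cdkn1a is also on this list. The log2 fold change of Zbtb16 was -5.74 without KO replicate 2. Without WT replicate 1, 2 or 3 the list had 2 higher and 2 lower each time, and with library totals 3 and 2. Of 15 cAMP-CREB induced genes 4 rose and 11 were not called (4 adjusted over the list alone, set adjusted p = 0.0809). The phosphodiesterases Pde4d and Pde4b rose by 1.04 and 1.01 log2 and the kinase Sik1 by 1.03. The cAMP set passed without KO replicate 2 (adjusted p = 0.0345), and without KO replicate 1 it had 6 higher and 2 lower.

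Several calls among respiratory chain genes were lost when 1 library was left out. In the fits that lost them the log2 fold changes were 0.69 to 0.80 for mt-Co2 and 0.69 to 0.95 for mt-Nd6. For Cox6c they were 0.53 to 0.70 and for Cox4i1 0.37 to 0.55, so lower power may account for these losses. Of 12 mitochondrially encoded genes 2 rose and 10 were not called (1 adjusted over the list alone, set adjusted p = 0.0699), mt-Co2 by 0.78 log2 and mt-Nd6, which overlaps mt-Nd5 on the opposite strand, by 0.89. The counts of mt-Co2 were low, from 5.01 ± 0.13 to 8.62 ± 1.03 CPM, while mt-Co1 took 1.38% to 1.81% of a library. They may therefore not reflect its transcript level, which was not tested. Without KO replicate 1, 8 genes rose and the set had adjusted p = 0.000225. Without WT replicate 1, 2 or 3 or KO replicate 3 0 genes of the list were called, and without KO replicate 2 there was 1. The adjusted p values were then 0.0707, 0.0753, 0.0637 and 0.0748 for mt-Co2 and 0.135, 0.108, 0.089 and 0.0891 for mt-Nd6, with 0.085 for mt-Nd6 without KO replicate 2 and 0.0598 and 0.0944 for the pair with library totals. A GC offset also ended both calls, with 0.56 log2 for mt-Co2 (adjusted p = 0.071) and 0.60 for mt-Nd6 (0.118), left 0 calls in the list and moved its median from 0.53 to 0.25. Upper-quartile scaling and a length offset ended that of mt-Nd6 (0.0529 and 0.0813). Of 22 nuclear-encoded genes 2 rose, 1 fell and 19 were not called (1 adjusted over the list alone, set adjusted p = 0.619, direction up against a median of -0.005). Ndufs3 fell by 0.95 log2, and Cox6c and Cox4i1 rose by 0.70 and 0.48, and each of the 3 overlaps a gene on the opposite strand. Cox6c lost its call without WT replicate 2 (adjusted p = 0.116), WT replicate 3 (0.0859) or KO replicate 3 (0.0711) and with library totals (0.065), and Cox4i1 without WT replicates 1, 2 or 3 (0.0673, 0.124 and 0.123) or KO replicates 2 or 3 (0.0581 and 0.088), with library totals (0.129) and with upper-quartile scaling (0.0509). Ndufs3 kept its call without each library. The nuclear counts were 0 higher without WT replicate 2, WT replicate 3 or KO replicate 3, 1 higher without KO replicate 2, 5 higher and 2 lower without KO replicate 1, and 0 higher and 5 lower with library totals.

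Several genes were close to absent in one genotype. Among the 8 largest increases, Stc1, the secreted hormone stanniocalcin, and Cox7b2 had 0 counts in WT and were at least 89.4-fold and 74.2-fold higher in KO at a floor of 3 counts per library. Tmem47, Fam111a, Xlr and Alkal1 had 1 or 2 counts in WT, and their KO to WT ratios were 1917 (95% interval 530.2 to 15830), 1604 (443.6 to 13250), 1481 (265.3 to 58520) and 702 (126 to 27760). Alkal1 had 557, 91 and 83 counts in KO replicates 1, 2 and 3. Actg2 is among the 8, and Ces1d, a carboxylesterase, had 4 counts in WT, 3 of them in WT replicate 3, and 1969 in KO. Among the 8 largest decreases, Cdkn1c, the imprinted p57 inhibitor of cell cycle kinases, and Cthrc1, a secreted collagen repeat protein, had 2 counts in KO, with WT to KO ratios of 2117 (585.6 to 17480) and 1885 (521.5 to 15570). Rps4l, which overlaps Tmtc1 on the opposite strand, Sncaip, Tert and Rnf144a had 1 count in KO each and ratios of 1041 (186.5 to 41180), 771 (138 to 30480), 768 (137 to 30360) and 756 (135 to 29900). Tert encodes the catalytic subunit of telomerase. Zic1 fell by 9.48 log2 with 6 counts in KO, and Fam213b fell by 9.15 with 4. The KO counts of Cdkn1c, Cthrc1, Rps4l, Zic1 and Fam213b lay in KO replicate 3 alone, those of Sncaip and Tert in KO replicate 1, and that of Rnf144a in KO replicate 2, and the WT counts of Xlr and Alkal1 lay in WT replicate 3. Rnf144a had 142, 138 and 446 counts in WT.

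In all, 4255 of 15009 tested genes (28.4%) changed, 2074 higher and 2181 lower in KO, and 2297 of them by at least 1 log2 (1003 higher, 1294 lower). KO and WT values did not overlap in 7448 genes (49.6%), against 10% by chance. Of 93 named genes past the test, 92 had no overlap of KO and WT values, and Prg4 did. The naming rule fixes most of this count. It requires no overlap for the largest changes and takes the list members with the smallest p. Scaling by library totals moved the median of all genes by -0.203 log2 and gave 1351 higher and 3347 lower, so changes here are relative to the TMM scale. The number of changed genes was 2643, 2298 and 2825 without WT replicates 1, 2 and 3 and 6537 without KO replicate 1.

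KO replicate 1 stood apart from the other KO libraries. The first principal component, 78.3% of the variance, separated the genotypes, and the second, 13.3%, placed KO replicate 1 at -56.6 and KO replicates 2 and 3 at 35.8 and 31.1. Across genes, which are not independent replicates, log2 CPM of KO replicate 1 correlated with those of KO replicates 2 and 3 at 0.968 and 0.970, against 0.992 between these and 0.989 to 0.991 among WT libraries. With KO replicate 1 left out, 4226 of the 4255 genes were called again, 0 of them with the other sign. The SRF-MRTF list then had 18 higher, the matrix list 20 higher and 3 lower, the brown and beige list 1 higher and 10 lower, the interferon list 10 lower, and the p53 list 15 of 15 lower.

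**Figure D3:**
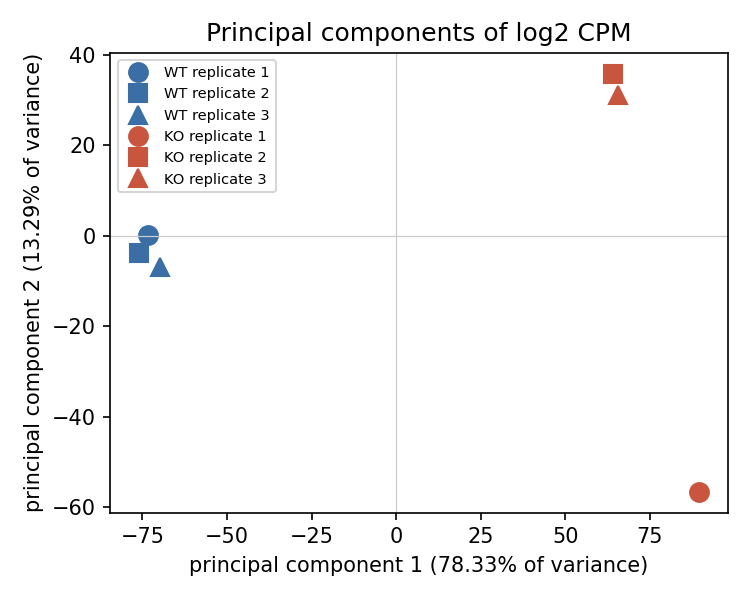
Principal components of log2 CPM over the tested genes, 1 point per library, coloured by genotype with symbols for replicates. The first component, 78.3% of the variance, parts KO from WT, and the second, 13.3%, parts KO replicate 1 from the other KO libraries.

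Genes of 5 chromosomes shifted as sets relative to the other genes. On chromosome 14, 176 of 470 tested genes were lower and 29 higher (median -0.40 log2, adjusted p = 2.14e-08), and on chromosome 10, 188 of 722 were lower and 61 higher (median -0.24, adjusted p = 0.000847). With an estimated correlation both kept their calls, with adjusted p = 0.00402 and adjusted p = 0.00663. Higher genes prevailed on chromosome X (123 against 35 of 470, median 0.25, adjusted p = 8.64e-05), chromosome 3 (181 against 75 of 797, median 0.27, adjusted p = 0.00215) and chromosome 18 (75 against 27 of 359, median 0.15, adjusted p = 0.0454). For these the values were adjusted p = 0.0664, 0.0693 and 0.0664 with an estimated correlation. Chromosome 18 lost its call without WT replicate 2 (adjusted p = 0.0807), WT replicate 3 (0.0744), KO replicate 2 (0.0926) or KO replicate 3 (0.0861), without genes changed over 4-fold (0.109), with library totals (0.0545) and with a GC offset (0.148). Around Actb itself, 25 of 130 genes within 5 Mb changed (19.2%), against 4229 of 14878 elsewhere (28.4%), an odds ratio of 0.60 (Fisher's exact test, two-sided, p = 0.019). Against the other genes of chromosome 5, of which 214 of 944 changed (22.7%), the difference did not pass the test (odds ratio 0.81, exact p = 0.432), a comparison chosen after the data were seen. The share near Actb stayed below that elsewhere in each fit with 1 library left out. It was 13.7% against 17.2%, 12.2% against 14.9% and 12.3% against 18.5% without WT replicates 1, 2 and 3 (exact p = 0.352, 0.46 and 0.0871). Without KO replicates 1, 2 and 3 it was 35.4% against 42.4%, 16.0% against 24.8% and 16.0% against 20.8% (exact p = 0.129, 0.0192 and 0.195).

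**Figure D4:**
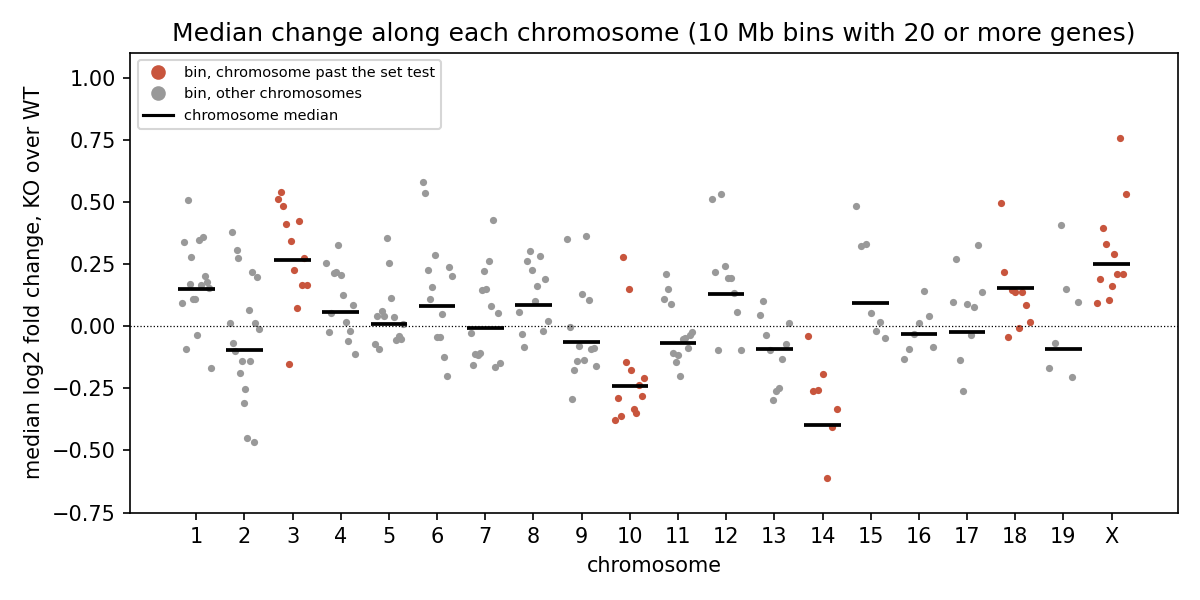
Median log2 fold change (KO over WT) of the tested genes in 10 Mb bins with at least 20 genes (points) and of each chromosome (black bars), red where the chromosome passed the set test. Chromosome 14 has the lowest median, -0.40, and chromosome 3 the highest, 0.27.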

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

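The GC offset for the chromosomes, the counts of list members by setting and the background of chromosome 5 were chosen after the data were seen, and the other alternatives before. Between 3848 and 5263 genes changed with RLE or upper-quartile scaling, library totals, DESeq2, limma-voom, either filter, the 10 most abundant genes left out, or a GC or length offset, against 4255. Library totals gave 1351 higher and 3347 lower, which follows from the shift of all genes by -0.203 log2. With a test against a log2 fold change of 1, 1159 genes passed. With the replicate number as a block, 3045 changed, and with a GC offset as well 1356 were higher, though the numbers do not pair the libraries and the block spends degrees of freedom. Leaving out single libraries gave 2298 to 6537 changed genes, 1003 to 3075 higher and 1295 to 3462 lower, lowest without WT replicate 2 and highest without KO replicate 1. Each of these fits except that without KO replicate 1 called fewer genes than the main fit, so calls lost there can reflect lower power. The Actb log2 fold change stayed between -5.94 and -5.10 and called throughout. Of 7 lists past camera, 0 passed with an estimated correlation, while 14 passed with fry, which does not compare a list with other genes, and 12 with library totals, the added ones being actin isoforms and the osteoblast, glucocorticoid, cAMP and mitochondrially encoded lists. With an estimated correlation 2 of 5 chromosomes passed. With a GC offset chromosome 13 passed (adjusted p = 0.0202) and chromosome 18 did not (0.148). Near Actb, the lower share held within 10 Mb (18.62%, p = 0.000465) and without KO replicate 2 (16.03%, p = 0.0192), by Fisher's exact test. The call was lost within 2 Mb (18.6%, exact p = 0.178), with the block (13.85%, exact p = 0.0788), without each of the other 5 libraries, and against the other genes of chromosome 5 alone (19.23% near Actb, exact p = 0.432), a background chosen after the data were seen. The share ran from 12.21% to 35.38% over single libraries left out. Where no reason is given, the cause was not tested. Over the 95 named genes other than Actb, 1604 of 1705 values kept their direction and side of the threshold, 96 lost the call, 5 gained one and 0 turned. Of 308 list values 275 kept theirs, 14 lost and 19 gained a call. Of 240 chromosome values 229 did, 10 lost and 1 gained one. Depth limits genes near the floor of 3 counts, 0.0777 to 0.111 CPM on library totals before TMM scaling. There, counts of 0 to 3 in a genotype give only bounds or wide intervals.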

Other observations

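The 4 lists in the next paragraphs and the tests in this part were chosen after the results were seen, except those of GC content or length and of depth in KO replicate 1 and the planned check of chromosomes without genes changed over 4-fold, so the counts describe the genes and are not independent evidence of a direction.

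Genes of MHC class I and antigen processing fell. Of 19 tested 16 fell, 0 rose and 3 were not called (17 called adjusted over the list alone), with a median of -1.58 log2 and adjusted p = 3.69e-12 over the 4 added lists, or adjusted p = 0.0448 with an estimated correlation. H2-D1, a classical class I heavy chain, fell by 3.72 log2 (from 1233 ± 50.9 to 93.4 ± 41.3 CPM), H2-Q7 fell by 5.09 and H2-Q6 fell by 4.93, though H2 genes are so alike that reads are assigned between them with less certainty. The peptide transporter Tap1 fell by 2.00 log2 and the immunoproteasome subunit Psmb8 fell by 2.80, while the light chain B2m had a log2 fold change of -0.50 (adjusted p = 0.171). The H2 genes, Tap1, Tap2, Tapbp, Psmb8 and Psmb9 all lie on chromosome 17. Their fall may thus not be that many separate changes. Chromosome 17 as a whole did not pass camera (median -0.025 log2, adjusted p = 0.481), and a difference between the lines in the stretch that holds these genes was not tested. On other chromosomes Psme1, Psme2, Nlrc5 and Erap1 fell, and B2m and Psmb10 were not called. Glycolysis genes rose, with 14 higher, 0 lower and 5 not called of 19 (16 called adjusted over the list alone, median 0.94, adjusted p = 2.45e-08, or adjusted p = 0.0779 with an estimated correlation). Pgk1 rose by 1.99 log2 (from 477 ± 44.4 to 1894 ± 251 CPM), Aldoa by 1.90, the glucose transporter Slc2a1 by 1.45 and Gapdh by 1.30. These directions held under RLE, upper-quartile and library-total scaling.

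Genes of the amino acid response driven by ATF4 fell, with 12 lower, 1 higher and 7 not called of 20 (13 called adjusted over the list alone, median -0.53, adjusted p = 2.63e-05, or adjusted p = 0.0453 with an estimated correlation). Shmt2, a mitochondrial serine enzyme, fell by 1.54 log2 (from 484 ± 45.2 to 166 ± 21.9 CPM), the cystine transporter Slc7a11 fell by 2.72 and the pseudokinase Trib3 fell by 1.38. The genes not called were Atf4 itself (-0.42 log2, adjusted p = 0.122), Asns (-0.55, 0.108), Atf5, Slc7a3, Nupr1, Cebpg and Ddit3. Ddit3 had 15153, 2335 and 2221 counts in KO replicates 1, 2 and 3 (1.16 log2, adjusted p = 0.313). The 1 higher gene, Vldlr, was not called without WT replicates 1, 2 or 3 or KO replicate 3, where 0 genes of the list were higher, and library totals gave 0 higher and 14 lower. Of 20 tested imprinted genes 8 fell, 4 rose and 8 were not called (13 called adjusted over the list alone, median -0.70, adjusted p = 0.0201, or adjusted p = 0.112 with an estimated correlation). Slc38a4 fell by 5.98 log2 (from 141 ± 11.5 to 2.23 ± 0.419 CPM), Nnat fell by 3.79, Sgce fell from 70.5 ± 2.68 to 24.9 ± 1.03 CPM, and Kcnq1ot1 and Grb10 rose by 1.42 and 0.91. The higher imprinted genes were 2 without WT replicate 3.

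With 3 libraries against 3 there are 10 splits, so no share under 0.05 can be reached. For changed genes the real split alone, 1 of 10, gave as many as its 4255, and the highest other gave 0. For lists 2 of 10 gave at least the real 7, the highest other 8 with WT replicates 1 and 2 beside KO replicate 2. Each grouping that mixes the genotypes gave 4 to 8 lists. For chromosomes 1 of 10 gave the real 5, and the highest other gave 3. A mixed grouping has unequal numbers of KO libraries on its sides, so it keeps part of the KO to WT difference. It also puts that difference into the spread within groups, which lowers its gene calls. The splits can therefore not decide how many genes, lists or chromosomes would pass without a difference between the genotypes.

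KO replicates 2 and 3 held more Actb, 3.14% and 2.68% of the WT mean, than KO replicate 1 at 0.553%. WT RNA or reads carried over would bring all abundant WT transcripts alike. The 14 genes at 20 CPM or more in WT and at most 3 counts in KO replicate 1 had medians of 0.338% and 0.39% of WT in those libraries against Actb excesses of 2.59% and 2.13%, which argues against it, with Robo1 at 3.3% in KO replicate 3 as the 1 gene above. Reads of Actg1 assigned to Actb would keep their ratio, but Actb per 100 Actg1 counts was 0.349, 1.63 and 1.53 in KO replicates 1, 2 and 3, at least 4.39 times the value of replicate 1. Transcripts of the disrupted locus that differ between cultures stay a possible explanation that was not tested, since the counts give no position within the gene.

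KO replicate 1 lay apart from the other KO libraries, with 2358 genes over 1 log2 from their mean against 411 between those libraries. Trends on GC content and length explained 0.857% of the variance of this difference, which argues against such a bias. After all KO libraries were thinned to 1 total, the correlation between KO replicates 2 and 3 still exceeded those of KO replicate 1 by 0.0215 or more, so lower depth does not account for it. Actb at 0.553% of the WT mean argues against a wrong genotype label. A different culture, passage or extraction stays open, as the labels give no batch, and no biological explanation was tested.

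The shifts of chromosomes 3, 10, 14, 18 and X may reflect the lines rather than the loss of Actb, since genotype and line cannot be separated here. With the GC trend removed chromosomes 3, 10, 14 and X kept at least 0.768 of their median shift and their calls, and without genes changed over 4-fold 4 of these 4 kept their calls, which argues against both as the whole cause for them. Chromosome 18 lost its call in both checks (adjusted p = 0.148 and 0.109, median 0.0788 and 0.136 log2 against 0.153), so both stay open for it. A copy number difference would shift most stretches of a chromosome alike. On the 5 called chromosomes 90.2% of 51 bins of 10 Mb had the chromosome's sign, against 64.9% of 174 elsewhere. Shuffled gene positions gave 94.1% to 100% (median 98%), so the choice of these chromosomes fixes a high share in advance. The observed share lay below that range, so the shifts were less even along these chromosomes than in shuffled genes. The bins with the chromosome's sign were 7 of 7 on chromosome 14, 11 of 11 on X and 11 of 12 on chromosome 3. On chromosomes 10 and 18 they were 10 of 12 and 7 of 9. Copy number and regional regulation cannot be told apart from these counts, and DNA was not analysed here.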
